A study of Homo sapiens with 6 samples.

How the data were processed

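RNA-seq was done on 6 samples of HCT116, an established human colorectal cancer cell line. Per the labels, 3 samples were wild type (WT) and 3 were treated with CSE, an abbreviation that the labels do not spell out. With smoking named in the series title, CSE is read here as cigarette smoke extract. Dose, exposure time and solvent control are not given in the sources used here. Groups and replicate numbers were taken from the labels.

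Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and made into libraries with a poly(A) mRNA kit for Illumina sequencing. The submitters' processing notes name FastQC 0.11.2, Trimmomatic 0.36, HISAT2 2.0, bedtools 2.26.0 and the genome build GRCh38, without the role or order of each. The counting program, the gene annotation and the strandedness of the libraries are not given in the sources used here. The authors deposited 1 table of TPM (length-corrected shares of transcripts) for 20263 genes in 6 libraries, with 2 decimals, and 0 of its sample columns were left unmapped. TPM divides by transcript length and by the library's total, so every column has the same total and the sequencing depth of each sample is unknown. No counting interval or detection floor was therefore computed, and no count model was used. Because TPM is a share, a change in a few abundant transcripts moves all others. Mitochondrially encoded genes held 25.5% to 30.2% of a library, so their share was followed and a rescaling without them was run. Where the counting could not use strand, overlapping and antisense genes cannot be separated, and near-identical paralogs such as HSPA1A and HSPA1B can exchange reads.

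The unit was the one the design assumed. Genes with a TPM of at least 1 in at least 3 libraries were kept (12793). Values were transformed to log2(TPM + 1), and CSE was compared with WT with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, no covariate). P values were adjusted by the Benjamini-Hochberg method at 0.05. All log2 fold changes are CSE minus WT on the log2(TPM + 1) scale, which understates the change of genes with low TPM. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

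The test, the filter, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. Of 592 list members, 2 had no line in the table. Lists with at least 3 tested members (28) were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. The tests were repeated with a correlation estimated per list, with ranks, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. The genes named are CKAP2L, STAT3, AREG and EGFR, which the series title names; the 8 largest rises and the 8 largest falls among genes with adjusted p under 0.05, a mean TPM of at least 5 in the higher group and no overlap between the groups, unnamed loci left out; and members of each list. From each list called by camera came the 3 called members with the largest change in its direction and the 1 with the largest change against it, and from each other list the 2 called members with the largest change. Any gene named outside this rule is given as an added value. Some genes that the rule takes are not reported here.

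Symbols were matched from Ensembl gene IDs for 20148 of 20263 genes, and positions on GRCh38 were taken from GENCODE 29 for 20224 of them, which need not be the annotation the authors used. The alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, a variance prior without trend, a robust prior, the replicate number as a block, and leaving out each sample in turn. Chosen after seeing the data were the removal of mitochondrially encoded genes with rescaling, limma's treat test against a 1.2-fold change, and the removal of a trend on transcript length and GC content for the lists. The 12 reference genes, 13 other glycolytic enzymes and symbol-root families in the last part were also chosen after seeing the data.

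The procedure was tested on simulated data for CSE against WT over 12793 genes with the spread of these samples. It recovered 8% of 50 genes changed 1.1-fold, 58% of 50 changed 1.25-fold, 98% of 50 changed 1.5-fold and 100% of 50 changed 2-fold, with 4 false calls and 0 sign errors. Only these genes were changed in the simulation, while 50.1% of the genes tested were called in the data. The adjustment of p values is stricter where few genes change, so these shares need not hold for the data. In 20 simulated comparisons without any change, 0 called a gene and 1 called a list. The simulated genes varied independently of each other. In the data the estimated correlation was 0.27 for the G2/M and mitosis list and 0.911 for ribosomal proteins. False calls of lists whose members move together were therefore not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.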

Results

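The data are TPM values of 20263 genes from 6 poly(A) RNA-seq libraries of HCT116 cells, a human colorectal cancer line that grows as an epithelial monolayer. The 3 WT samples were compared with 3 samples treated with CSE, read here as cigarette smoke extract. The series title asks how smoking acts on colorectal cancer through CKAP2L, STAT3, AREG and EGFR. Between 12640 and 12778 genes reached 1 TPM in a sample, and between 3724 and 3923 were listed at 0. The depth of the libraries is unknown.

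The groups stood apart in the whole profile. The first principal component held 76.9% of the variance and separated CSE from WT. The second held 9.26% and set CSE replicate 3 (score -9.31) apart from CSE replicate 1 (4.35) and CSE replicate 2 (5.70). Pearson's r across genes, which are not independent replicates, was 0.998 to 0.999 within groups and 0.988 to 0.990 between them. Mitochondrially encoded genes held 27.0%, 28.6% and 30.2% of the TPM in the WT samples and 25.8%, 25.8% and 25.5% in the CSE samples. Ribosomal protein genes held 11.3%, 11.1% and 10.7% in WT and 11.8%, 11.7% and 12.6% in CSE, with the highest share in CSE replicate 3.

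Of the 4 genes in the series title, AREG and CKAP2L rose with CSE, EGFR fell slightly and STAT3 did not pass the test. AREG encodes amphiregulin, a secreted ligand of the EGF receptor (ENSG00000109321, chromosome 4, 74445134 to 74455009, plus strand). It went from 258 ± 8.80 TPM in WT to 459 ± 8.43 in CSE (SD, n = 3 each), a 1.78-fold rise (log2 fold change 0.83, SE 0.0377, limma adjusted p = 1.72e-13). CKAP2L encodes a protein of the mitotic spindle (ENSG00000169607, chromosome 2, 112736607 to 112764677, minus strand). It rose from 19.4 ± 0.373 to 26.8 ± 1.91 TPM, 1.38-fold (log2 fold change 0.44, SE 0.0554, limma adjusted p = 1e-06). EGFR, the receptor itself (ENSG00000146648, chromosome 7, 55019021 to 55211628, plus strand), was at 42.6 ± 1.16 TPM in WT and 37.9 ± 4.30 in CSE (log2 fold change -0.17, SE 0.0607, limma adjusted p = 0.0238). STAT3, a transcription factor activated by cytokine and growth factor receptors (ENSG00000168610, chromosome 17, 42313324 to 42388568, minus strand), was at 112 ± 1.64 and 108 ± 5.83 TPM (log2 fold change -0.055, SE 0.043, limma adjusted p = 0.301). For all 4 genes the values are of mRNA and say nothing of phosphorylation or secreted protein.

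Over all genes tested, 3 of the 4 title genes passed, and 3 passed when adjusted over the list alone; the study may have picked these genes from these samples, so the second count is not independent evidence. The EGFR call rested on single samples: without CSE replicate 3 the log2 fold change was -0.076 (limma adjusted p = 0.13), without WT replicate 1 it was -0.15 (0.118) and without WT replicate 3 it was -0.18 (0.0536). It also ended without the filter on low values (0.119) and without the variance trend (0.0898), and STAT3 passed as lower when mitochondrially encoded genes were left out (log2 fold change -0.11, limma adjusted p = 0.0262).

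**Figure D1:**
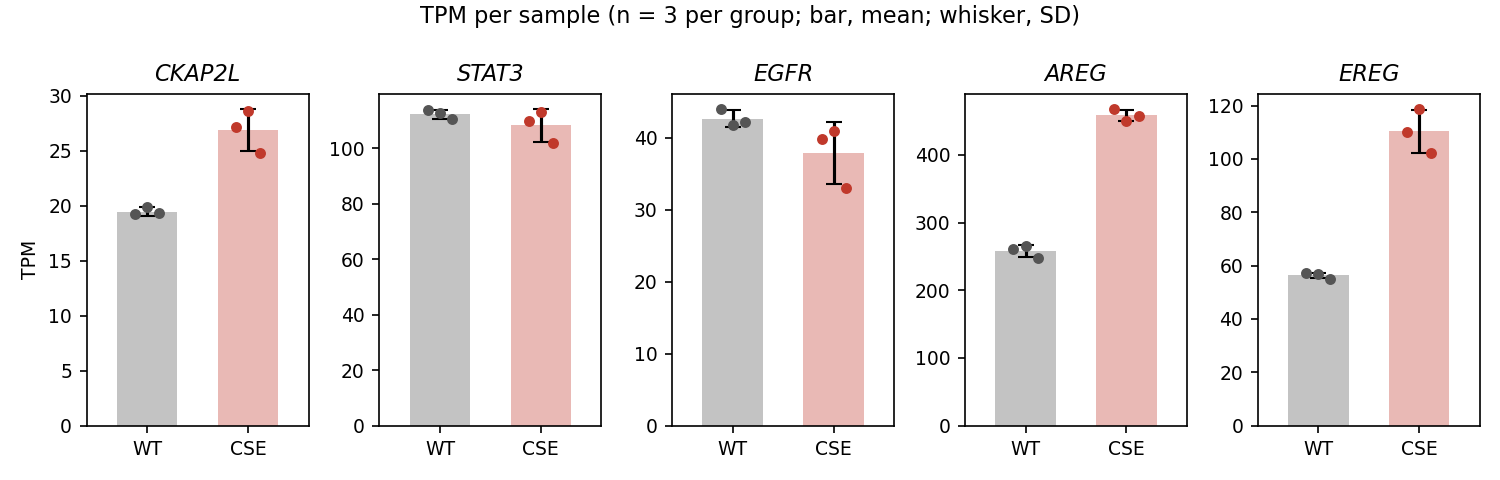
TPM of CKAP2L, STAT3, EGFR, AREG and EREG in the 3 WT (grey) and 3 CSE (red) samples; points are samples, bars are means and whiskers are SDs, and each panel has its own axis from 0. AREG lies at 258 TPM in WT and 459 in CSE, while STAT3 overlaps between groups and the lowest EGFR value belongs to CSE replicate 3.

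Across the transcriptome, many genes changed by a little and few by much. Under the rule for named genes, which ranks on the log2(TPM + 1) scale, CYP24A1 showed the largest rise and LCN2 the largest fall. Of 12793 genes tested, limma called 6407 (50.1%), of which 3130 were higher and 3277 lower in CSE. The median size of a called change was 0.25 on the log2 scale, or 1.19-fold. A change of at least 1.5-fold was called for 370 genes (155 higher, 215 lower) and of at least 2-fold for 49 (15 higher, 34 lower). The 2-fold count depends on the pseudocount and was larger with 0.1, as given in the section on processing. The 3 values of each group did not overlap for 7342 genes (57.4%, against 10% by chance). The split of calls by direction depends on the scaling: 48.9% of calls were higher in CSE with TPM as deposited, and 34.3% when mitochondrially encoded genes were left out and the rest rescaled, which moved the median of all genes to -0.06. Tested against a change of 1.2-fold, a setting chosen after seeing the data, 891 genes passed (431 higher, 460 lower).

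The largest rise was that of CYP24A1, the mitochondrial enzyme that inactivates vitamin D, from 22.8 ± 1.17 to 76.3 ± 5.24 TPM (3.34-fold, log2 fold change 1.70, SE 0.0532, limma adjusted p = 1.91e-16). DHRS2, a short-chain dehydrogenase, rose 3.02-fold from 16.6 to 50.3 TPM, and the Wnt ligand gene WNT16 rose 3.15-fold from 4.34 to 13.7 TPM. RNF43, a ubiquitin ligase that removes Wnt receptors from the cell surface, rose 2.66-fold from 8.40 to 22.3 TPM. SCG2, a granin of secretory vesicles, rose 2.53-fold from 13.1 to 33.2 TPM. HMMR, a spindle-associated hyaluronan receptor, rose 2.28-fold from 37.5 to 85.3 TPM. The monocarboxylate transporter family gene SLC16A6 rose 2.44-fold from 3.81 to 9.29 TPM, and TNS2, a focal adhesion protein gene, rose 2.27-fold from 8.77 to 19.9 TPM.

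LCN2, which encodes the iron-siderophore-binding lipocalin-2 (chromosome 9, 128149071 to 128153455), fell furthest, from 144 ± 3.31 to 20.2 ± 1.93 TPM (7.14-fold lower, log2 fold change -2.78, SE 0.0539, limma adjusted p = 3.8e-20). The keratin-associated protein gene KRTAP2-3 fell from 129 to 33.4 TPM (3.86-fold lower), the carboxypeptidase gene CPA4 from 99.6 to 27.9 TPM (3.57-fold) and the secreted protease inhibitor gene SLPI from 33.8 to 9.10 TPM (3.71-fold). BEST1, a chloride channel gene, fell from 17.6 to 4.83 TPM (3.64-fold), and SPX, a peptide hormone gene, from 5.17 to 1.32 TPM (3.91-fold). The secreted serine protease gene KLK5 fell from 71.7 to 26.4 TPM (2.71-fold). JUN, a subunit of the AP-1 transcription factor, fell from 125 to 46.7 TPM (2.68-fold). All 16 of these genes kept their direction and passed in every alternative setting in which they were tested against no change.

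**Figure D2:**
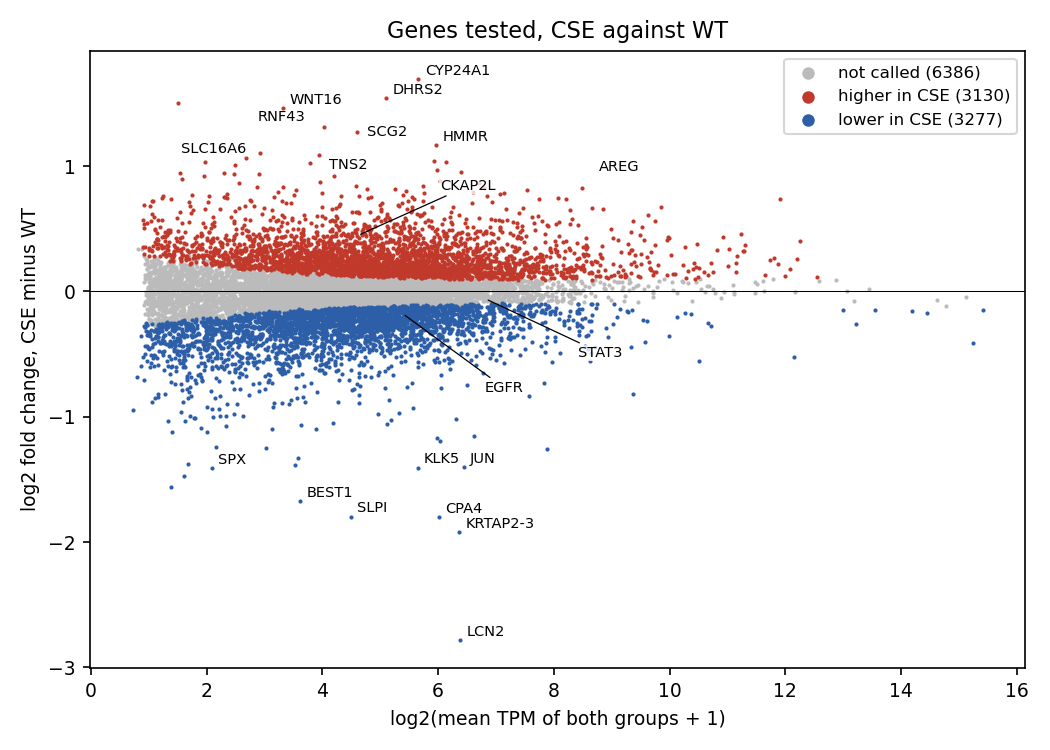
Log2 fold change, CSE minus WT, against log2(mean TPM + 1) for the 12793 genes tested; each point is a gene, red if called higher (3130), blue if called lower (3277) and grey if not called, and the title genes and the 16 genes of largest change are labelled. LCN2 lies lowest, at -2.78, and CYP24A1 highest among the labelled genes, at 1.70.

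Genes of mitosis, cholesterol synthesis, hypoxia with glycolysis, replication-dependent histones, ribosomal proteins and metallothioneins moved up as lists, and immediate early, ribosome biogenesis and mitochondrially encoded genes moved down. In all, camera called 9 of the 28 lists tested (6 up, 3 down). None of the 9 held with an estimated correlation (0 lists). Fry, which does not compare a list with other genes, called 18 (8 up, 10 down), among them lists that camera did not call.

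All 28 genes of the G2/M and mitosis list rose, and all 28 rose adjusted over the list alone (median log2 fold change 0.51, camera adjusted p = 1.56e-23). The adjusted p = 0.432 with an estimated correlation. HMMR led (log2 fold change 1.17), followed by the mitotic kinesin gene KIF20A (1.04) and the centromere protein gene CENPF (1.04). In the list of G1/S and DNA replication genes, 7 of 26 rose and 13 fell (7 and 14 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.321). The transcription factor gene E2F1 fell (log2 fold change -0.59) while RRM2, a ribonucleotide reductase subunit gene, rose (0.57). Of 18 histone genes fixed, 10 were not tested under the filter, and the 8 tested rose, also when adjusted over the list alone (median 0.66, camera adjusted p = 0.000118, adjusted p = 0.443 with an estimated correlation). H1-2 (33.2 TPM in WT), H2BC12 (30.6) and H2BC5 (20.7) were the members well above 1 TPM, and the members named by the rule lay near 1 TPM, where rises help a gene pass the filter. Without the filter 15 were tested, of which 8 rose and 7 did not pass (median 0.32). The libraries were poly(A)-selected and most replication-dependent histone mRNAs lack a poly(A) tail, so these values do not measure their full output. H2AC20 had a log2 fold change of 0.95, H2AC11 of 0.90 and H3C10 of 0.75, or 2.04, 1.35 and 1.34 with a pseudocount of 0.1. H2AC20 was listed at 0 in WT replicate 3, had a log2 fold change of 0.48 without that sample, and missed the threshold with the robust prior (limma adjusted p = 0.17) and without the filter (0.0695).

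Of 26 cholesterol synthesis genes, 20 rose, 0 fell and 6 did not pass, with the same counts adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 1.61e-07, adjusted p = 0.758 with an estimated correlation). The sterol transporter gene STARD4 rose by 0.48 and HMGCS1 by 0.43. In the hypoxia and glycolysis list 17 of 22 rose and 3 fell, or 18 and 3 adjusted over the list alone (median 0.25, camera adjusted p = 1.29e-05, adjusted p = 0.758 with an estimated correlation). The glucose transporter gene SLC2A3 rose by 0.57, PFKFB4 by 0.57 and the mitophagy gene BNIP3 by 0.54, while the carbonic anhydrase gene CA12 fell by 0.61 on the log2 scale.

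Ribosomal protein genes rose in 13 of 24 cases and fell in 0, with 15 rising adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 0.000444, adjusted p = 0.837 with an estimated correlation). RPS2 rose by 0.40, RPL10A by 0.37 and RPS24 by 0.33. Under quantile normalization the list was no longer called (camera adjusted p = 0.934), with RPL10A at 0.13 and RPS24 at 0.21. The list holds only part of the ribosomal protein genes: of all 47 tested symbols with the root RPL, a set formed after the data were seen, 23 were higher and 4 lower, namely RPL27 (-0.18) and the ribosomal-protein-like genes RPL22L1, RPL7L1 and RPL26L1. Genes of ribosome biogenesis, which work in the nucleolus, moved the other way, with 13 of 20 lower and 2 higher, the same adjusted over the list alone (median -0.18, camera adjusted p = 0.0114, adjusted p = 0.837 with an estimated correlation). RRS1 (-0.44), RRP12 (-0.38) and PPAN (-0.36) fell, while the nucleolar chaperone gene NPM1 rose (0.17, or 0.099 under quantile normalization and 0.11 with mitochondrially encoded genes left out).

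Of 19 immediate early genes 11 fell and 4 rose, the same adjusted over the list alone (median log2 fold change -0.28, camera adjusted p = 0.0025, adjusted p = 0.837 with an estimated correlation). JUN fell by 1.40, CCN2 by 0.87 and CCN1 by 0.77 on the log2 scale, whereas EGR1 rose from 442 to 594 TPM (0.43). In the metallothionein and zinc list MT1E (0.72), MT1X (0.57) and MT2A (0.41) rose and the zinc exporter gene SLC30A1 fell (-0.20), so 3 of 5 rose and 1 fell, the same adjusted over the list alone (median 0.41, camera adjusted p = 0.0309, adjusted p = 0.837 with an estimated correlation). That call was lost without CSE replicate 3 (camera adjusted p = 0.128), without the filter (0.0813), with median-of-ratios scaling (0.109), with quantile normalization (0.0976) and with ranks (0.134).

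Of the 13 mitochondrially encoded genes 7 were lower and 0 higher, the same adjusted over the list alone (median log2 fold change -0.15, camera adjusted p = 0.038, adjusted p = 0.837 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, went from 44290 ± 2418 to 33210 ± 365 TPM (-0.41), MT-ND1 changed by -0.26 and MT-ND4L by -0.17. The value of MT-ND4L was -0.081 without CSE replicate 3 (limma adjusted p = 0.142), and its call was also lost without WT replicate 2 (0.0562) or WT replicate 3 (0.114), without the filter (0.252), with median-of-ratios scaling (0.119), with quantile normalization, without the variance trend (0.0908) and with the robust prior (0.0519). Under quantile normalization that of MT-CO1 was -0.18. The list's call was lost without WT replicate 2 (camera adjusted p = 0.0646), WT replicate 3 (0.177), CSE replicate 1 (0.0589) or CSE replicate 2 (0.0733), and also without the filter (0.188), at a mean TPM of at least 5 (0.0507), with median-of-ratios scaling (0.183), with quantile normalization (0.964) and with fry (0.0564).

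**Figure D3:**
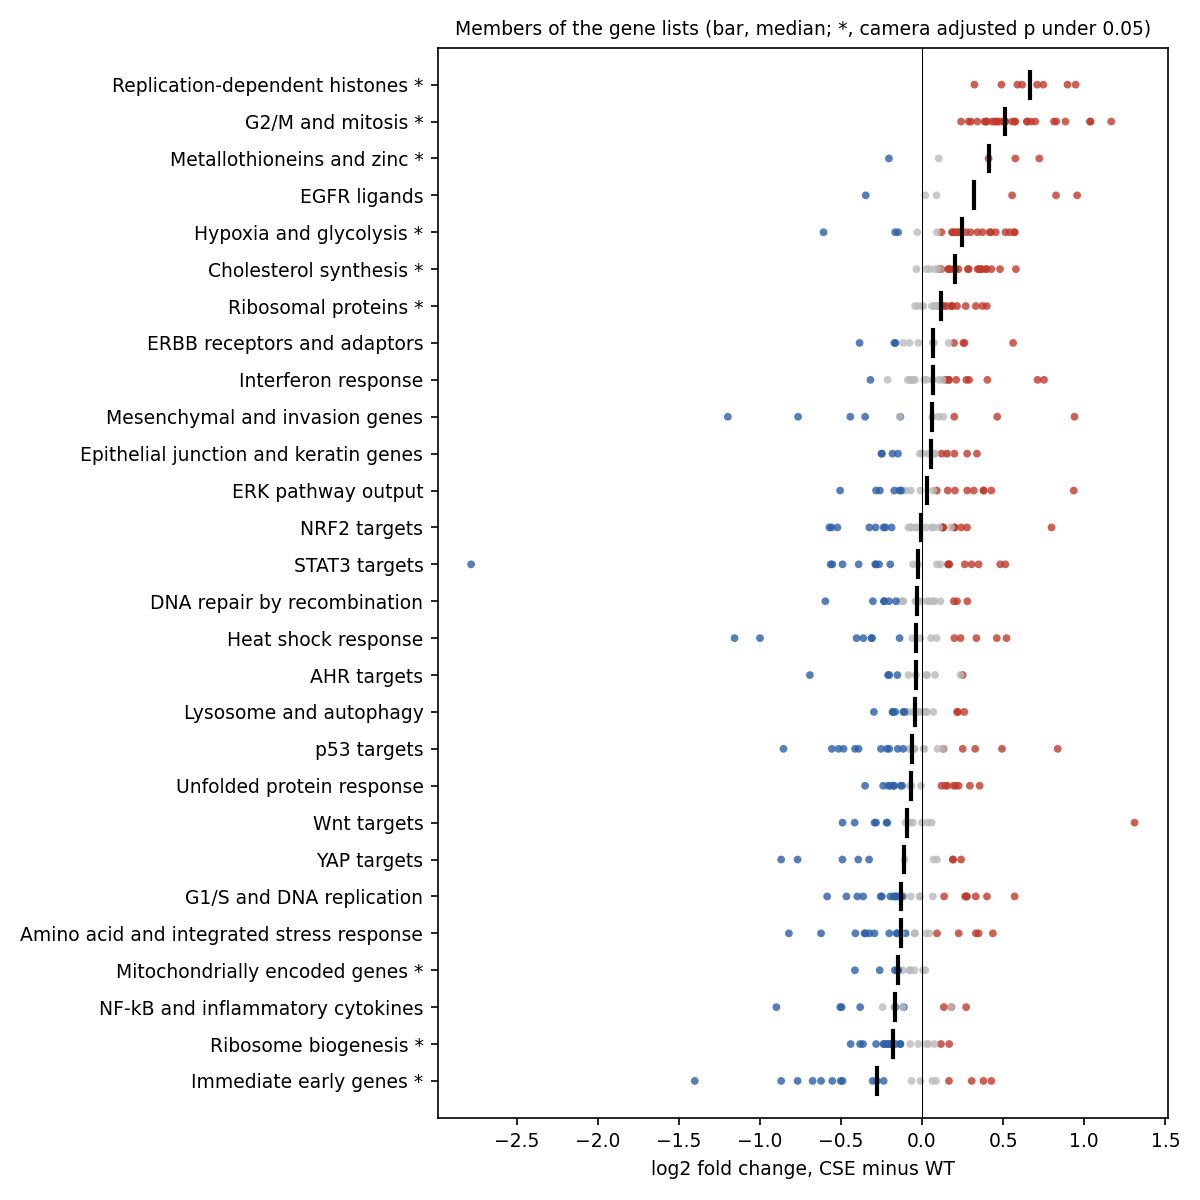
Log2 fold change, CSE minus WT, of each tested member of the 28 lists, in order of their medians (black bars); points are genes, red if called higher, blue if called lower and grey if not called, and an asterisk marks the 9 lists called by camera. All 28 G2/M genes lie to the right of 0, between 0.24 and 1.17.

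The lists closest to the series title were not called by camera. Among 6 tested EGFR ligands 3 rose and 1 fell, the same adjusted over the list alone (median log2 fold change 0.32, camera adjusted p = 0.057). EREG, which encodes epiregulin and is the nearest tested gene to AREG on chromosome 4, rose 1.96-fold from 56.3 ± 1.11 to 110 ± 8.11 TPM (log2 fold change 0.96, SE 0.0479, limma adjusted p = 7.05e-13). The list passed without WT replicate 2 (camera adjusted p = 0.0289), CSE replicate 1 (0.0146) or CSE replicate 2 (0.0242), and also with mitochondrially encoded genes left out (0.039) and with fry (0.00781). Among 13 ERBB receptors and adaptors 4 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.473), with the EGFR inhibitor gene ERRFI1 higher (0.56, or 0.36 under quantile normalization) and LRIG1 lower (-0.39). ERK pathway output had 9 of 20 genes higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.398); ETV1 rose (0.94) and MYEOV fell (-0.51). Of 21 STAT3 targets 8 rose and 9 fell (9 and 9 adjusted over the list alone, median -0.03, camera adjusted p = 0.398), and fry called the list lower (adjusted p = 0.0145). The largest changes among them were falls, those of LCN2 (-2.78) and of the anti-apoptotic gene BCL2L1 (-0.56).

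The lists of aryl hydrocarbon, antioxidant, heat shock, amino acid stress, p53, DNA repair and unfolded protein responses were not called by camera either. Metallothioneins, given above, were called higher (camera adjusted p = 0.0309), a call that several settings lost. Fry called lower the targets of the aryl hydrocarbon receptor (adjusted p = 0.0465), heat shock (0.0101), the amino acid and integrated stress response (0.0101) and p53 targets (0.0335). Of 11 targets of the aryl hydrocarbon receptor 1 rose and 4 fell (2 and 4 adjusted over the list alone, median log2 fold change -0.04, camera adjusted p = 0.473). CYP1A1, the enzyme that aryl hydrocarbons induce, fell from 4.55 ± 0.392 to 2.44 ± 0.247 TPM (-0.69, SE 0.0866, limma adjusted p = 9.96e-07), and CYP2S1 rose (0.25). Of 26 NRF2 targets, the antioxidant response, 8 rose and 8 fell, the same adjusted over the list alone (median -0.01, camera adjusted p = 0.839), with ABCC2 higher (0.80) and GCLM lower (-0.57). Heat shock genes numbered 5 higher and 7 lower of 16, the same adjusted over the list alone (camera adjusted p = 0.473). HSPA1B fell from 134 to 59.6 TPM (-1.16) and its near-identical copy HSPA1A from 4.74 to 1.87 TPM, both uncertain as single genes because reads may be split between them. In the amino acid and integrated stress response 5 of 21 rose and 11 fell, the same adjusted over the list alone (median -0.13, camera adjusted p = 0.0617); asparagine synthetase ASNS fell from 840 to 475 TPM (-0.82) and ATF3 fell as well (-0.62). That list passed without WT replicate 2 (camera adjusted p = 0.0478) or CSE replicate 1 (0.0491) and under quantile normalization (0.00846). Of 26 p53 targets 5 rose and 11 fell, the same adjusted over the list alone (camera adjusted p = 0.189), with TP53I3 higher (0.84) and EDA2R lower (-0.85). DNA repair by recombination had 3 of 22 higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.529); XRCC2 (-0.60) and FANCB (-0.30) fell. The unfolded protein response had 8 of 19 higher and 8 lower, the same adjusted over the list alone (camera adjusted p = 0.905), with CALR higher (0.35) and DNAJB9 lower (-0.35). Its median (-0.07) and mean were negative while the test pointed up.

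Among inflammatory genes, CXCL8 fell from 12.9 to 6.48 TPM (log2 fold change -0.90) and CXCL1 from 6.95 to 4.64 TPM (-0.50). The NF-kB and inflammatory cytokine list had 3 of 14 higher and 7 lower (3 and 9 adjusted over the list alone, camera adjusted p = 0.152, fry adjusted p = 0.0111). Interferon response genes numbered 9 higher and 1 lower of 23 (7 and 1 adjusted over the list alone, camera adjusted p = 0.153, fry adjusted p = 0.0137), with IFIT2 (0.75) and IFIT3 (0.71) higher. Wnt targets had 1 of 14 higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.152); RNF43 rose (1.31) and MYC fell from 466 to 332 TPM (-0.49). YAP targets had 3 of 11 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.152), with CCN2 (-0.87) and CCN1 (-0.77) lower, and passed without CSE replicate 1 (0.039) and with fry (0.0101).

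Epithelial junction and keratin genes had 5 of 16 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.518), with KRT19 (0.34, or 0.22 under quantile normalization) and CLDN3 (0.28) higher. Mesenchymal and invasion genes had 3 of 13 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.698), and fry called the list lower (adjusted p = 0.0247). SPARC rose from 2.78 to 6.25 TPM (0.94); the median of the list was 0.06 and its mean -0.08. Lysosome and autophagy genes had 3 of 18 higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.473), with CTSB lower (-0.30). Intestinal differentiation and markers of other cell types each had 2 tested members and no list test. CDX2 rose from 8.85 to 10.2 TPM (limma adjusted p = 0.0284) and KRT20 did not pass (4.47 and 4.78 TPM). The collagen gene COL1A1 fell from 43.8 to 37.3 TPM and CD68, a lysosomal gene used as a macrophage marker, from 17.6 to 12.1 TPM.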

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

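Leaving out mitochondrially encoded genes, the test against 1.2-fold and the removal of a length and GC trend were chosen after the data were seen; the other settings were planned. The causes of the changes below were not tested. Over the other settings with limma's test against no change, the number of genes that differ lay between 5463 and 6924 (6407 as reported). Leaving out 1 sample gave 5463 to 6573 genes, 47 to 56 of them at least 2-fold, and 8 to 11 lists. The count of at least 2-fold rose from 49 to 120 (39 higher, 81 lower) with a pseudocount of 0.1, which understates low genes less. The 34 lower genes became 21 at a mean TPM of at least 5, where fewer genes are tested, and 52 with mitochondrially encoded genes left out. The test against 1.2-fold called 891 genes (431 higher, 460 lower).

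AREG and CKAP2L passed as higher in every setting with a test against no change. The log2 fold change of STAT3 was -0.11 and passed with mitochondrially encoded genes left out. That of EGFR stayed at -0.17 without the filter and without the variance trend but missed the threshold, and lay between -0.23 and -0.076 when 1 sample was left out. Of 1155 values of the 78 other genes that the rule takes, under alternatives, 1144 kept direction and side of the threshold, 11 missed the threshold (H2AC20 and MT-ND4L) and 0 reversed.

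With an estimated correlation 0 lists were called (0 higher, 0 lower), and with fry 18, of which 10 lower. The unfolded protein response, not called in any of these settings, turned to lower with median-of-ratios scaling (adjusted p = 0.923), quantile normalization (0.548), the replicate block (0.951), mitochondrially encoded genes left out (0.976), ranks (0.938) and the length and GC trend removed (0.966), and without WT replicate 3 (0.963) or CSE replicate 3 (0.877), and ranged from 0.775 to 0.963 when 1 sample was left out. Epithelial junction and keratin genes turned to lower under quantile normalization (0.934).

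With the replicate number as a block, 6537 genes, 49 of at least 2-fold and 7 lists were called, against 6407, 49 and 9; metallothioneins (0.0893) and mitochondrially encoded genes (0.156) were the lists lost, and MT-ND4L (0.124) was the named gene lost. The deviations of same-numbered samples correlated at -0.07, 0.02 and -0.09, and the highest correlation (0.12) joined WT replicate 1 with CSE replicate 3. These values gave no sign that the numbers pair the samples, but so few samples cannot exclude a pairing. Depth is unknown, so how far it limits genes of low TPM is unknown too.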

Other observations

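The reference genes, glycolytic enzymes, the window around GAPDH and gene families below were chosen after their values were seen, as were all tests of explanations here except the splits of the samples. The length and GC correction was chosen then too, but before its own result was seen.

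GAPDH, the glycolytic enzyme gene often used to normalise RT-qPCR, rose from 2878 ± 24.4 to 4793 ± 90.4 TPM (SD, n = 3 each), 1.67-fold (log2 fold change 0.74, SE 0.0373, limma adjusted p = 8.48e-13). Its rise ranked 1 among the 91 tested genes with a mean of at least 1000 TPM, and its log2 fold change was 0.74 with median-of-ratios scaling, 0.59 with quantile normalization and 0.68 with mitochondrially encoded genes left out. ACTB (1920 and 1852 TPM, log2 fold change -0.05), B2M (0.01), TBP (-0.04), GUSB (0.02) and SDHA (0.08) did not pass. Of 12 common reference genes 4 were higher, 3 lower and 5 not called. The AREG transcript was 1.84-fold higher in CSE relative to ACTB and 1.83-fold relative to TBP, but 1.07-fold relative to GAPDH (log2 difference 0.09, SE 0.041). CKAP2L was 1.43-fold higher relative to ACTB and 0.827-fold, that is lower, relative to GAPDH (log2 difference -0.27, SE 0.05). EREG was 2.03-fold higher relative to ACTB and 1.17-fold relative to GAPDH. CKAP2L was higher relative to 11 of the 12 reference genes (1.13-fold to 1.53-fold) and lower relative to GAPDH alone. The smallest of these rises was relative to PPIA (log2 difference 0.17, SE 0.099) and is not clearly above 0. That relative to RPLP0 was 0.19 (SE 0.08).

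Of 13 other glycolytic enzyme genes 12 were higher as well, including TPI1 (0.50), PGAM1 (0.49), ALDOC (0.45) and GPI (0.43), and PFKP (0.03) did not pass. ALDOC, PGK1, ENO2 and LDHA are also members of the hypoxia and glycolysis list, so the counts overlap. The fold change of ENO1 (0.15) turned to -0.06 under quantile normalization. Within 0.5 Mb of GAPDH on chromosome 12, 22 of 36 other tested genes were higher and 5 lower (median 0.21). Among those higher were the glycolytic genes TPI1 and ENO2 (0.22), and also NCAPD2 (0.56) and CDCA3 (0.63). Of all 12793 genes tested, 3130 were higher and 3277 lower, with a median of -0.004. The cause of the rises in this window was not tested.

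Symbols with the root RPL passed as higher (camera adjusted p = 0.0441, adjusted p = 0.996 with an estimated correlation), but not under median-of-ratios scaling (0.157), with mitochondrially encoded genes left out (0.17) or under quantile normalization (0.917). Those with the root RPS were not called (15 of 41 higher, 4 lower, camera adjusted p = 0.152), and the 4 lower were the kinase family genes RPS6KA1, RPS6KA2, RPS6KA4 and RPS6KL1.

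Keratin-associated protein genes and several keratins were lower in CSE. Among 424 families formed by symbol root with at least 5 tested members, camera called 8, and 0 with an estimated correlation. Besides KRTAP, KRT and RPL, CDKN (7 of 10 higher, 0 lower), HMGN and NDUFB were called up. HSPA (9 of 13 lower, 2 higher) and ZBTB were called down. CDKN, HMGN, NDUFB, HSPA and ZBTB were no longer called under median-of-ratios scaling. All 7 KRTAP genes were lower, from KRTAP2-3 (log2 fold change -1.92) to KRTAP4-7 (-0.53), with a median of -0.68 (camera adjusted p = 0.00149, adjusted p = 0.996 with an estimated correlation), and the family stayed called under median-of-ratios scaling (0.0308), with mitochondrially encoded genes left out (0.0313) and under quantile normalization (0.0471). The SE was 0.0516 for KRTAP2-3 and 0.0855 to 0.14 for the other members. Where members such as KRTAP2-2, KRTAP2-3 and KRTAP2-4 are alike in sequence, they can exchange reads and are not separate observations. Of 16 symbols with the root KRT 10 were lower and 2 higher (camera adjusted p = 0.0243, adjusted p = 0.996 with an estimated correlation), though this call ended under median-of-ratios scaling (0.0693) and with mitochondrially encoded genes left out (0.0824). KRT7 fell from 330 to 138 TPM (-1.25), and KRT17 (-1.24), KRT80 (-1.06) and KRT15 (-1.02) fell, while KRT19 (0.34) and KRT23 (0.27) rose.

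The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 6407 genes, against 0 for the highest of the others. For changes of at least 2-fold it was 49 against 0 (1 split as large), and for gene lists 9 against 7 (1 split as large). Every other split mixes the groups, so the difference between CSE and WT adds to its spread and makes gene calls unlikely. Part of that difference also remains in each of them, and they gave 3 to 7 lists.

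Mitotic genes rose together and CKAP2L rose with them. Bias by gene length and GC content is argued against, since the median of the G2/M list was 0.51 before and 0.503 after a trend on both was removed. A larger share of cycling cells of every phase alike is argued against by the G1/S list, with a median of -0.128 (SD over members 0.279) and 13 of 26 members lower. Against that, 7 members including RRM2 rose, so a shift of cells toward later S phase stays open. The 8 of 15 histone genes that rose without the filter cannot weigh on this, because poly(A) libraries capture these mRNAs poorly. The change of CKAP2L lay at percentile 28.6 of the G2/M list, with 8 of its 28 members smaller, so its rise may be part of the general mitotic rise, for example of more cells in G2 or M, though an effect of CSE itself on CKAP2L remains open.

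AREG, EREG and BTC, EGFR ligand genes that lie beside each other among the tested genes of chromosome 4, were all higher in CSE, BTC at low TPM (1.62 to 2.84, log2 fold change 0.56). A gain of the region in the CSE cells could raise all 3, but the 20 other tested genes within 2 Mb of AREG had a median of -0.133, with 1 higher and 5 lower, and the highest (0.192) lay below BTC. CXCL8 and CXCL1 in the same window fell (-0.90 and -0.50). This argues against a gain of the whole window and leaves regulation shared by the ligand genes, or by a smaller segment, as a hypothesis that was not tested.

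The following genes were picked, after their values were seen, among genes that stress or aryl hydrocarbons induce. CYP1A1, JUN, ATF3, HSPA1B and ASNS were lower in CSE, while MT1E (0.72), EGR1 (0.43), MT2A (0.41), DDIT3 (0.35) and DDIT4 (0.33) were higher. An exchange of the labels of the whole groups could give the falls but would leave these rises to be accounted for. Correct labels would in turn leave the falls to be accounted for. The genes were picked, so their balance decides nothing, and an exchange cannot be told apart from a true fall. Of CYP1B1, TIPARP, AHRR, NQO1 and ALDH3A1, 0 were called lower and 0 higher. Reads moved between HSPA1A and HSPA1B are argued against, since the summed TPM of both differed by -1.162 (SE 0.036) on the log2 scale. Handling that raised all immediate early genes in WT is argued against, since 4 of the 19 tested were called higher in CSE; handling that raised some of them was not tested and stays open. A late or adapted response to CSE also remains possible and untested, because the exposure time is not given in the sources used here.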
